A study of Populus tremula x Populus alba with 20 samples.

How the data were processed

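Apical buds of 4 overexpressor lines and WT were profiled at 2 harvests, with 2 replicates per line and harvest. Per the labels' protocols, RNA was extracted from ground frozen buds with a CTAB buffer, and libraries were made with a stranded mRNA kit for Illumina sequencing. The deposited values are whole-number read counts per gene, 1 table per harvest with the same 31823 genes in the same order. The submitters' processing notes name HISAT2 as a tool, with no version. The counting program, the genome build, the use of strand in counting and any filter are not given in the sources used here. Reads of near-identical gene copies and of overlapping genes may therefore be split or lost in ways the counts do not show. Per the labels, WT replicate 1 at SD8 matched a column whose name carries an extra digit, and no other sample matched it.

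Groups were taken from the genotype and treatment labels. The labels give 6 weeks of long days in one place and 4 in another, and 3 buds or 2 plants per replicate. They call the replicates biological. Replicates were compared by a chi-square test over genes with at least 20 counts in the pair, and the chi-square per degree of freedom ran from 6.75 to 29.6, so no pair was treated as 1 library.

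Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries scaled by TMM, and groups compared with the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Within a harvest the 10 libraries were fitted in 3 groups, TEML1ox (n = 4), TEML2ox (n = 4) and WT (n = 2). Chilling in WT and the interaction of construct and harvest came from 1 fit of all 20 libraries. Each line was also compared with WT in a fit of 5 groups of 2. Lines of a construct were pooled as replicates, so the p-values of the pooled fits count libraries of a line as independent. The SE of a log2 fold change was computed as its absolute value over the square root of F and is approximate. CPM values used TMM-scaled totals, and principal components used log2 CPM with a prior count of 2. Where a group was at 0 counts, the fold was bounded with 3 counts over the group, which covers counting error only.

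The test was tried on simulated counts with 200 changed genes of at least 1 CPM per comparison. For TEML1ox against WT it recovered 67% of 2-fold and 96% of 4-fold changes at SD8 (26947 genes) and 84% and 98% at CH2 (25696 genes). For TEML2ox against WT it recovered 69% and 94% at SD8 and 88% and 99% at CH2. On 27337 genes it recovered 69% and 90% for chilling in WT, 56% and 90% for the TEML1ox interaction and 51% and 87% for the TEML2ox interaction. False calls made up 2.13 to 7.88% of the calls. These simulations drew spread at the level of the fitted dispersions with no line effect. Overlaps between comparisons that share WT were set against 20 simulations of unchanged groups. These drew spread from the fit with each line as its own group, so no difference between lines, WT included, entered them. The biological coefficient of variation of that fit was 0.118 at SD8 and 0.0906 at CH2, against 0.191 and 0.106 with lines pooled.

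The rule for named genes was fixed before the data were examined. Without names it takes, per comparison, up to 2 identifiers that rose and 2 that fell with the largest log2 fold change, among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the libraries compared. The overlap condition has no meaning for an interaction and was not applied there. Lists of gene families and pathways had also been fixed, but they match on names, the files do not pair identifiers with names, and so every list was void and its tests were not run. Checks of GC content and gene length were not run, as no annotation was used here.

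Alternatives fixed before the data were examined were RLE scaling, DESeq2 1.42.0, no low-count filter, a filter of 50 counts in 2 libraries, limma-voom (limma 3.58.1), the replicate number as a block, each library left out, each line as its own group, an adjusted p under 0.01, the fit of all 20 libraries, and limma-voom with the line as a random block. A fit without the TEML2_2ox line, and for the overlap of the constructs one with a separate WT library for each, were added after seeing the data. Other splits of the libraries and all 45 pairs of the 10 libraries of a harvest were refitted.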

Results

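The series measured polyadenylated RNA in apical buds of hybrid poplar (Populus tremula x Populus alba), from an INRA clone widely used for transformation. Buds came from wild-type plants (WT) and from 4 transgenic lines that overexpress a TEMPRANILLO-like protein. TEMPRANILLO proteins are plant transcription factors known from Arabidopsis as repressors of flowering. The lines TEML1_1ox and TEML1_2ox carry one construct (TEML1ox) and the lines TEML2_1ox and TEML2_2ox the other (TEML2ox). Plants were harvested after 8 weeks of short days, when growth had ceased and buds had set (SD8), or after 2 further weeks of short days at 4 °C (CH2). The series title places the work in the release of bud dormancy, which chilling promotes in trees. Each line and WT had 2 replicates per harvest, which gave 20 libraries in 10 groups. The labels describe each replicate as a pool of buds but differ on whether it held 2 plants or 3 buds. WT was the control used here.

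The count tables listed 31823 genes, and the total per library ran from 35779227 to 39352645. Totals averaged 37515522 ± 1085910 counts at SD8 and 38434339 ± 637912 at CH2 (SD, n = 10 each). Genes with at least 10 counts numbered 26035 ± 225 at SD8 and 24893 ± 117 at CH2 (SD, n = 10). The difference was 1142 genes (2-sided permutation test, p = 2e-05). The permutation took libraries as independent, although each line gave 2 per harvest, and the harvests came as separate tables. The gene with the most counts took 4.14 ± 1.16% of each SD8 library and 3.19 ± 0.640% of each CH2 library (SD, n = 10). Replicates correlated at r of 0.988 to 0.993 across genes on the log2 scale, where genes are not independent replicates. Every pair differed by more than sampling noise. The files do not pair the gene identifiers with names, so genes are given by identifier alone, and the overexpressed genes are not singled out by name.

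At SD8 the first principal component held 43.7% of the variance and set both TEML2_2ox libraries, at -75.5 and -75.8, apart from the other 8, which lay between -33.8 and 50.5. At CH2 the first component held 21.3% and the second 18.1%. Both WT libraries lay highest on the second component, at 38.7 and 28.3, against 20.4 or less in the 8 overexpressor libraries.

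**Figure D1:**
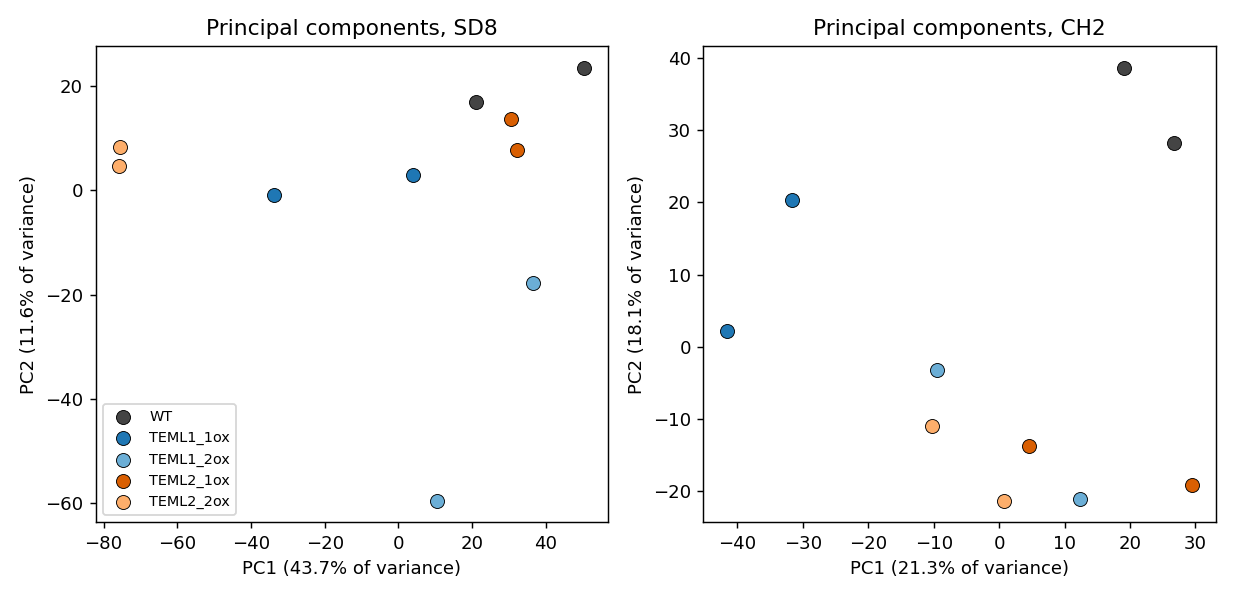
Principal components of log2 CPM (counts scaled by TMM and the library total) at SD8 (left) and CH2 (right). Each point is 1 library coloured by line, and the axes give arbitrary component units with the share of variance. TEML2_2ox lies near -75 on PC1 at SD8, and the WT pair lies at 28.3 and 38.7 on PC2 at CH2.

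The first question was whether the overexpressors differed from WT before chilling. No gene passed the threshold in either construct at SD8. The gene with the smallest adjusted p, PtXaAlbH.01G328000.v5.1, was chosen after its values were seen. It stood at 36.03 ± 7.21 CPM (counts scaled by TMM and the library total) in WT (SD, n = 2), 16.7 ± 1.13 in TEML1ox and 16.6 ± 1.88 in TEML2ox (SD, n = 4 each). Its log2 fold change was -1.11 ± 0.13 (SE) for TEML1ox and -1.12 ± 0.13 for TEML2ox, with edgeR adjusted p of 0.128 and 0.117, so it is not called at SD8. Its effect differed between harvests in TEML2ox, as given in the last paragraph. For TEML1ox edgeR called 0 of 26947 genes, with 1972 at an unadjusted p under 0.05. DESeq2 called 71 genes, limma-voom 0, the fit of all 20 libraries 14, and a model with each line as its own group 73. For TEML2ox edgeR also called 0 genes, with 2904 at an unadjusted p under 0.05, while DESeq2 called 208, limma-voom 0, the fit of all 20 libraries 49 and the model by line 1144. Leaving out TEML1_1ox replicate 1 gave 1 gene for TEML1ox, and leaving out TEML1_2ox replicate 1 or 2 gave 5 or 2 for TEML2ox. The biological coefficient of variation was 0.191 with lines pooled and 0.118 with each line as its own group.

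Line by line at SD8, TEML2_2ox differed from WT at many more genes than the other 3 lines. TEML1_1ox had 70 genes past the threshold, TEML1_2ox 32 and TEML2_1ox 33. TEML2_2ox had 6353, of which 3469 were higher and 2884 lower than in WT. The direct test between TEML2_2ox and TEML2_1ox gave 5483 genes, against 6 between the TEML1ox lines. Genes that passed in both lines of a construct in one direction numbered 10 for TEML1ox, 3 of them higher. For TEML2ox they numbered 23, 14 of them higher. Unchanged groups simulated against shared controls gave means of 0 and 0.1 such genes, which is chance with no effect and with hardly any calls to share. The simulations held only the spread within lines, and no difference of WT as a line. Across genes the log2 fold changes of the lines correlated at r = 0.48 for TEML1ox and 0.32 for TEML2ox, against 0.50 simulated for each, with covariances of 0.160 and 0.146 against 0.0501 simulated for each. These shared counts rested on single libraries. For TEML1ox they ran from 2 without either TEML2_2ox replicate to 270 without TEML1_2ox replicate 2, with 48 without WT replicate 2 and 4 to 6 without TEML1_1ox replicate 1 or 2, TEML1_2ox replicate 1, TEML2_1ox replicate 2 or WT replicate 1. For TEML2ox they were 7 without TEML2_1ox replicate 2, 8 without either TEML2_2ox replicate, 9 and 15 without WT replicates 1 and 2, and 59 without either TEML1_2ox replicate.

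**Figure D2:**
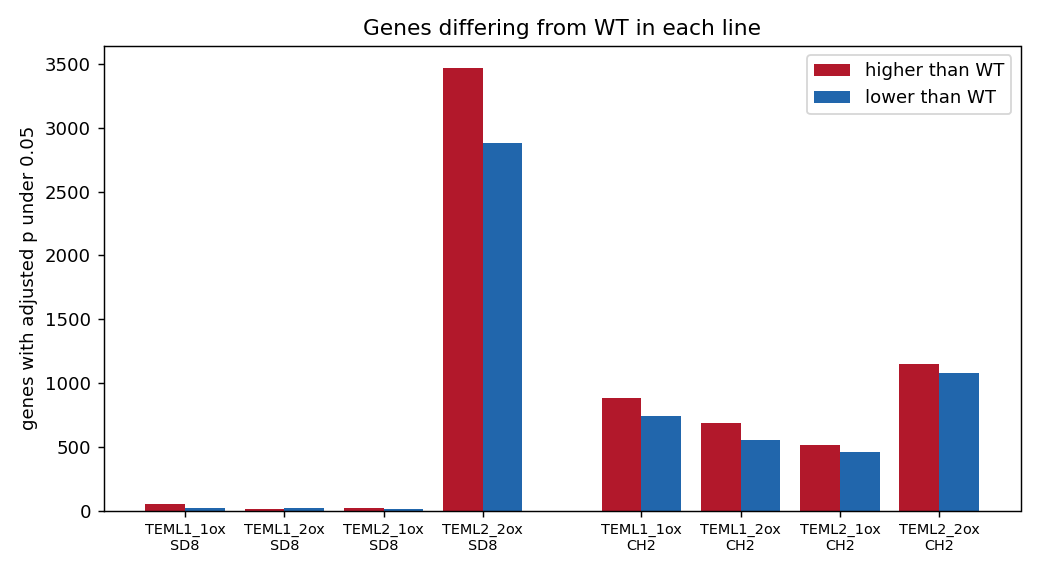
Genes past the threshold against WT in each line at SD8 and CH2. The vertical axis counts genes with an adjusted p under 0.05, red for higher and blue for lower than WT, from 2 libraries per line and 2 of WT. TEML2_2ox at SD8 has 3469 higher and 2884 lower genes, against 32 to 70 in all in the other lines at that harvest.

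After chilling, TEML1ox buds differed from WT buds at 959 of 25696 genes, 595 higher and 364 lower. Most differences were small, with a median absolute log2 fold change of 0.41 and 90 genes at 2-fold or more, 44 of them higher and 46 lower. PtXaAlbH.17G012500.v5.1 was at 4.87 ± 2.43 CPM in TEML1ox (SD, n = 4) and 1.65 ± 0.153 in WT (SD, n = 2), a log2 fold change of 1.56 ± 0.39 (SE, edgeR adjusted p = 0.0472). PtXaAlbH.04G014200.v5.1 was at 4.47 ± 0.832 CPM against 1.71 ± 0.203, a log2 fold change of 1.38 ± 0.22 (edgeR adjusted p = 0.00947). It was also higher in TEML2ox, at 1.00 ± 0.22 (edgeR adjusted p = 0.0234), a call lost without either WT or either TEML2_2ox replicate. PtXaAlbH.18G093200.v5.1 had 0 counts in all 4 TEML1ox libraries and 6.90 ± 0.0888 CPM in WT, at least 352-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 1.02e-06). PtXaAlbH.07G094900.v5.1 also had 0 counts in TEML1ox and 9.45 ± 0.732 CPM in WT, at least 482-fold lower on the same floor (edgeR adjusted p = 0.04998). Both of these last genes were also at 0 elsewhere. PtXaAlbH.18G093200.v5.1 was at 0 in 1 TEML1_1ox and 1 TEML2_2ox library at SD8. PtXaAlbH.07G094900.v5.1 was at 0 in 13 of the 20 libraries, among them both of TEML2_2ox at CH2 and both of WT and of TEML2_1ox at SD8, so its absence at CH2 was shared by a TEML2ox line. The floor covers counting error only. PtXaAlbH.18G093200.v5.1 stayed past the threshold with each library left out, and PtXaAlbH.04G014200.v5.1 did so except without WT replicate 1 or 2 (edgeR adjusted p up to 0.132). PtXaAlbH.17G012500.v5.1 did not pass without WT replicate 1 or 2, TEML1_2ox replicate 2 or any 1 of the 4 TEML2ox libraries, nor with the replicate number as a block (edgeR adjusted p up to 0.297). Of the libraries left out in turn, PtXaAlbH.07G094900.v5.1 passed only without TEML2_2ox replicate 1 or 2 (edgeR adjusted p up to 0.214 without the others). It also missed the threshold with the replicate number as a block in edgeR and in DESeq2 (adjusted p of 0.0801 and 0.0559). The count rested on both WT libraries: leaving out WT replicate 1 left 11 genes and leaving out WT replicate 2 left 30, while leaving out TEML1_2ox replicate 2 left 384 and TEML1_1ox replicate 1 left 638. With TEML2_2ox out of the fit it was 537. The model moved it as well: limma-voom with the line as a random block gave 323 genes, the fit of all 20 libraries 277 (211 higher and 66 lower), the replicate number as a block 578, each line as its own group 1899 and DESeq2 2024.

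**Figure D3:**
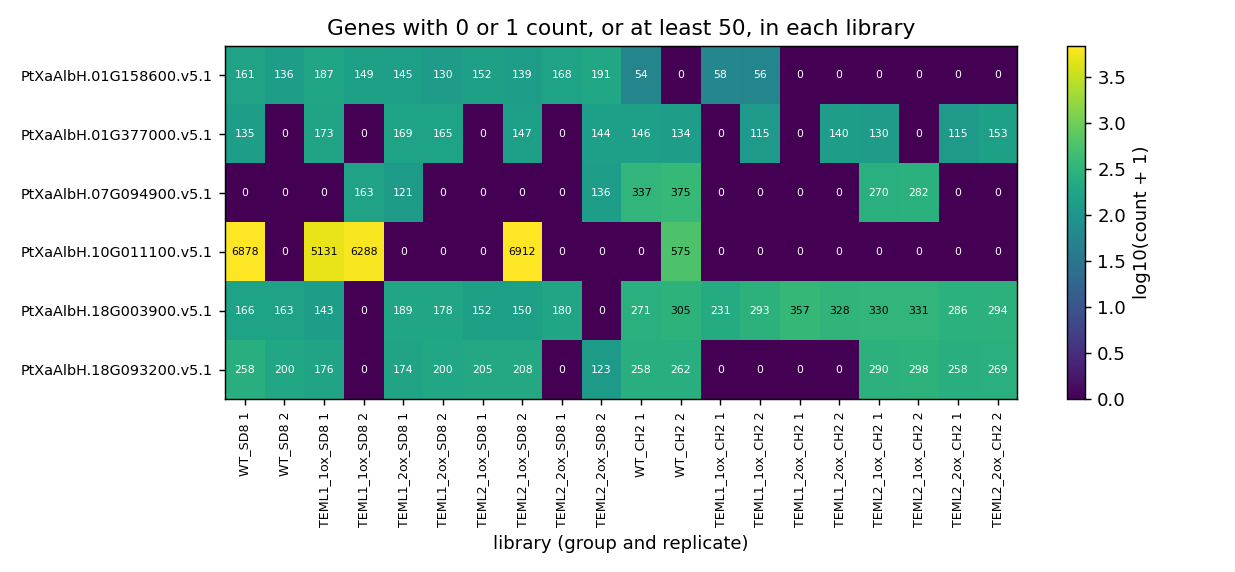
Counts of 6 genes in each of the 20 libraries, as numbers and as colour on a log10(count + 1) scale. Each cell is 1 library, with 0 in dark blue. PtXaAlbH.18G093200.v5.1 is at 0 in all 4 TEML1ox libraries at CH2 and also in 1 TEML1_1ox and 1 TEML2_2ox library at SD8.

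TEML2ox buds differed from WT buds at 1609 of the 25696 genes at CH2, 886 higher and 723 lower, with a median absolute log2 fold change of 0.39. At 2-fold or more, 31 were higher and 54 lower. PtXaAlbH.08G098800.v5.1 was at 254 ± 86.2 CPM in TEML2ox (SD, n = 4) and 47.4 ± 0.337 in WT (SD, n = 2), a log2 fold change of 2.42 ± 0.26 (SE, edgeR adjusted p = 0.00172). PtXaAlbH.06G053700.v5.1 was at 2.71 ± 0.535 CPM against 1.13 ± 0.0916, a log2 fold change of 1.26 ± 0.30 (edgeR adjusted p = 0.0294). PtXaAlbH.19G011300.v5.1 fell by 2.50 ± 0.28 on the log2 scale, from 6.89 ± 0.558 CPM in WT to 1.21 ± 0.445 (edgeR adjusted p = 0.00184). PtXaAlbH.08G071200.v5.1 stood at 1.83 ± 0.541 CPM in TEML2ox, against 7.77 ± 0.00332 in WT, a log2 fold change of -2.08 ± 0.29 (edgeR adjusted p = 0.00475). Both of these genes were also lower in TEML1ox, by log2 fold changes of -3.36 ± 0.30 for PtXaAlbH.19G011300.v5.1 (edgeR adjusted p = 0.000564), which passed with each library left out, and -1.91 ± 0.28 for PtXaAlbH.08G071200.v5.1 (edgeR adjusted p = 0.00791), which did not pass without WT replicate 1 or 2. In TEML2ox, without WT replicate 1 or 2, PtXaAlbH.08G071200.v5.1 and PtXaAlbH.06G053700.v5.1 did not pass (edgeR adjusted p up to 0.0694 and 0.196), and the latter was also lost without TEML2_2ox replicate 1 or 2. This count also rested on both WT libraries, with 24 genes without WT replicate 1 and 54 without WT replicate 2. Leaving out TEML2_2ox replicate 1 gave 636, replicate 2 gave 721, and leaving out that whole line gave 46. Limma-voom with the line as a random block gave 767 genes, the fit of all 20 libraries 695 (474 higher and 221 lower), each line as its own group 2649 and DESeq2 2709.

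Both constructs differed from WT at many of the same genes at CH2. Of the calls, 405 were higher in both and 217 lower in both, and 0 were opposite, where independent lists would share 20.5 and 10.2. Because both comparisons use the same WT pair, unchanged groups were simulated against shared controls and shared 0.1 genes on average. That is chance with no effect, and does not tell how many real calls a deviation of the WT pair would make common. The simulated spread was that within lines only. A difference of WT as a line could therefore raise the covariance over the simulated one without an effect of the constructs, at either harvest. The log2 fold changes correlated at r = 0.69 across genes, against 0.68 simulated with no effect. Their covariance was 0.111 against 0.0397 simulated. A fit added after seeing the data gave each construct its own single WT library. With WT replicate 1 for TEML1ox and 2 for TEML2ox, r was 0.24 and the covariance 0.0975. With the WT replicates exchanged, r was 0.21 and the covariance 0.0865. No WT library entered both comparisons there, so the spread of single WT libraries was not shared. A difference of WT as a line still was. No simulation was run for these fits. A lone WT library lowers the number of calls by itself, so shared calls were not compared there. Part of the excess of shared calls may come from the shared controls. At SD8, where 0 genes were called, the covariance was larger still, at 0.251 against 0.0509 simulated (r = 0.78 against 0.68), and 0.241 and 0.228 with separate WT libraries (r = 0.35 and 0.33), so it did not follow the calls. Line by line, TEML1_1ox had 1624 genes, TEML1_2ox 1243, TEML2_1ox 972 and TEML2_2ox 2225. Both TEML1ox lines shared 543 genes in one direction, 336 higher and 207 lower. Both TEML2ox lines shared 722, 424 higher and 298 lower. These shared counts fell to 29 and 12 without WT replicate 1 and to 58 and 19 without WT replicate 2. The TEML1ox count was also 124 and 204 without TEML1_2ox replicates 1 and 2, 228 without TEML1_1ox replicate 1, and 286 and 285 without TEML2_2ox replicates 1 and 2. The TEML2ox count was 221 and 61 without TEML2_1ox replicates 1 and 2, and 91 and 193 without TEML2_2ox replicates 1 and 2. The direct tests between lines gave 20 genes within TEML1ox and 17 within TEML2ox.

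With lines pooled in edgeR the constructs differed from each other at few genes. DESeq2 and a model with each line as its own group called more at both harvests, as listed below. At SD8 the 1 gene past the threshold was PtXaAlbH.08G098800.v5.1, lower in TEML1ox at 21.2 ± 2.01 CPM than in TEML2ox at 183 ± 78.5 (SD, n = 4 each), a log2 fold change of -3.10 ± 0.29 (SE, edgeR adjusted p = 0.0148). Its level differed between the TEML2ox lines, with 115 ± 5.42 CPM in TEML2_1ox and 250.5 ± 0.221 in TEML2_2ox (SD, n = 2 each), against 32.6 ± 8.71 in WT. The SD8 call was lost without any 1 of the 4 TEML1ox libraries and with the replicate number as a block (edgeR adjusted p up to 0.184). At CH2 26 genes passed, 13 in each direction. PtXaAlbH.08G098800.v5.1 again differed, with 32.6 ± 3.59 CPM in TEML1ox (SD, n = 4) and a log2 fold change of -2.96 ± 0.20 (edgeR adjusted p = 5.18e-05). PtXaAlbH.10G102000.v5.1 was higher in TEML1ox, at 281 ± 43.1 CPM against 151 ± 21.7 in TEML2ox, a log2 fold change of 0.90 ± 0.12 (edgeR adjusted p = 0.0274). Against WT it was higher in TEML1ox by 0.96 ± 0.15 (edgeR adjusted p = 0.00834), except without WT replicate 1 or 2. At SD8 the same gene stood at 134 ± 7.37 CPM in TEML1ox, 18.0 ± 9.41 in TEML2ox and 28.4 ± 16.9 in WT, with an edgeR adjusted p of 0.156 between the constructs. PtXaAlbH.16G081200.v5.1 was also higher in TEML1ox, at 8.05 ± 1.17 CPM against 3.77 ± 0.851 (edgeR adjusted p = 0.0274). PtXaAlbH.18G093200.v5.1, at 0 counts in TEML1ox, was at 7.16 ± 0.515 CPM in TEML2ox, at least 365-fold higher. It and PtXaAlbH.08G098800.v5.1 passed at CH2 with each library left out. PtXaAlbH.10G102000.v5.1 and PtXaAlbH.16G081200.v5.1 did not pass without WT replicate 1 or 2, TEML1_1ox replicate 2, TEML1_2ox replicate 2, TEML2_1ox replicate 1 or 2 or TEML2_2ox replicate 1, and the latter also without TEML2_2ox replicate 2 or with the replicate number as a block (edgeR adjusted p up to 0.108 for both). The CH2 count of 26 was 68 without TEML1_2ox replicate 1, 40 without TEML1_1ox replicate 1, 10 without TEML2_2ox replicate 2, 3 without TEML2_2ox replicate 1 and 2 without any 1 of the other 6 libraries, and DESeq2 gave 390.

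**Figure D4:**
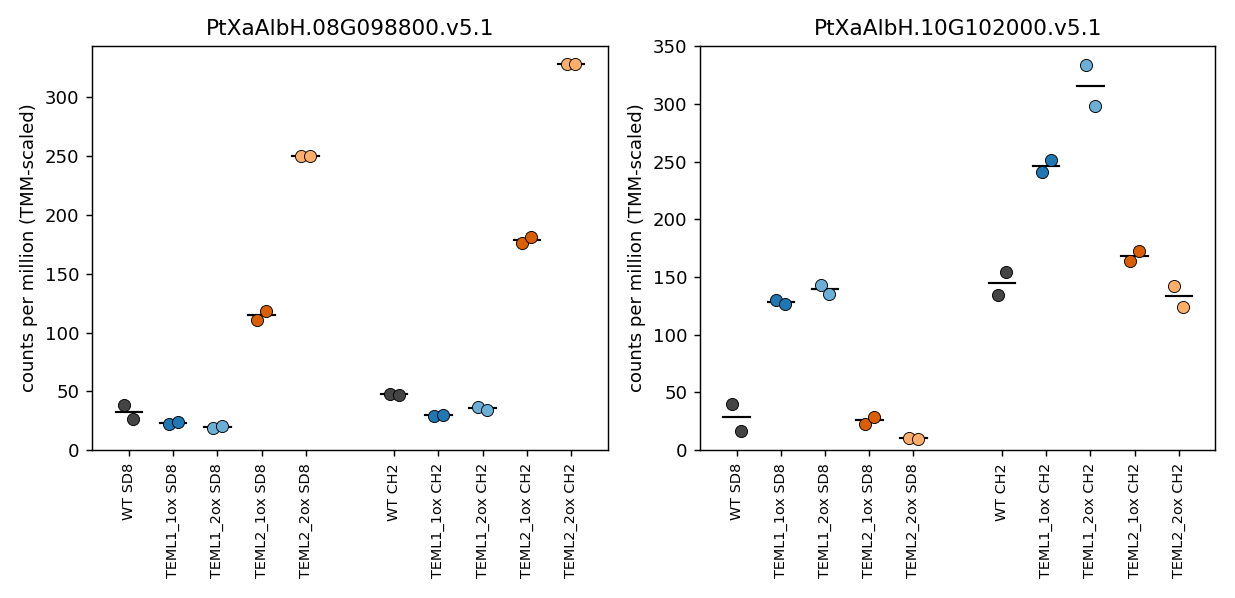
Level of 2 genes in each library, in TMM-scaled CPM. Points are single libraries, black bars the mean of the 2 replicates, and columns the lines at SD8 and CH2. PtXaAlbH.08G098800.v5.1 runs from 111 to 328 CPM in the TEML2ox libraries and stays at 47.7 or below in the others, and PtXaAlbH.10G102000.v5.1 is highest in the TEML1ox libraries at both harvests.

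Most of the bud transcriptome in WT differed between the harvests. Of 27337 genes, 16776 passed the threshold, 8116 higher and 8660 lower at CH2 than at SD8. At 2-fold or more, 2710 were higher and 4988 lower. PtXaAlbH.11G115600.v5.1 rose from 0.0664 ± 0.0940 CPM to 36.4 ± 1.204 (SD, n = 2 each), a log2 fold change of 9.32 ± 1.21 (SE, edgeR adjusted p = 6.56e-06). Its SD8 counts were 0 and 5, so the size of this change rested on 1 library: it was 8.36 without WT replicate 1 at SD8, and without replicate 2 it was fitted at 13.58 against a library at 0, which is no bound. PtXaAlbH.07G094900.v5.1 was at 0 counts in WT at SD8 and at 9.45 CPM at CH2, at least 240-fold higher against the 3-count floor (edgeR adjusted p = 0.0422). This gene is the one named above that was also at 0 in other libraries, and its call was lost without any 1 of the 4 WT libraries, with an edgeR adjusted p of up to 0.142. PtXaAlbH.01G190500.v5.1 was at 3.96 ± 1.80 CPM at SD8 and at 0 counts in both CH2 libraries, at least 99-fold lower (edgeR adjusted p = 0.000383). PtXaAlbH.13G066900.v5.1 went from 3.69 ± 0.688 CPM to 0 counts, at least 92-fold lower (edgeR adjusted p = 6.56e-07). TEML1ox had 19647 genes changed between the harvests and TEML2ox 20399, with 4 libraries per harvest rather than 2. WT and TEML1ox shared 15411 of these genes in one direction, WT and TEML2ox 15298. Harvest and the chilling treatment coincide in time, so the comparison covers chilling together with 2 further weeks. Each harvest also came as its own count table. Any difference in preparation, sequencing or processing between the harvests cannot be told apart from chilling.

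The last question was whether the effect of a construct differed between harvests. For TEML1ox 2 genes passed the interaction test. PtXaAlbH.11G031500.v5.1 was at 33.95 ± 2.00 CPM in TEML1ox and 39.5 ± 5.27 in WT at SD8, and at 12.9 ± 1.54 and 6.72 ± 1.67 at CH2, an interaction of 1.16 ± 0.18 on the log2 scale (SE, edgeR adjusted p = 0.0486). PtXaAlbH.14G087000.v5.1 had an interaction of -1.78 ± 0.22 (edgeR adjusted p = 0.00445), with 11.5 ± 0.771 CPM in TEML1ox and 6.03 ± 0.830 in WT at SD8 and 15.5 ± 2.25 and 28.0 ± 4.00 at CH2. For TEML2ox 56 genes passed, 35 positive and 21 negative. PtXaAlbH.11G031500.v5.1 was among them, at 1.39 ± 0.18 (edgeR adjusted p = 0.00806), with 14.4 ± 0.607 CPM in TEML2ox at CH2. So was PtXaAlbH.14G087000.v5.1, at -1.18 ± 0.22 (edgeR adjusted p = 0.0356), so both TEML1ox genes passed for TEML2ox too. Both interactions subtract the same WT libraries, so a deviation of WT would enter both and the constructs are not independent here. PtXaAlbH.01G328000.v5.1, not called at SD8, had an interaction of 0.98 ± 0.16 for TEML2ox (edgeR adjusted p = 0.0356) and 0.96 ± 0.16 for TEML1ox (edgeR adjusted p = 0.0552, not called). PtXaAlbH.14G005800.v5.1 had an interaction of 1.33 ± 0.24, PtXaAlbH.05G194300.v5.1 one of -1.56 ± 0.24 and PtXaAlbH.13G075600.v5.1 one of -1.48 ± 0.26, with edgeR adjusted p of 0.0356, 0.0253 and 0.0356. Without WT replicate 1 at SD8 both counts were 0 and no interaction named here passed. That was the one library whose loss ended the TEML1ox call of PtXaAlbH.14G087000.v5.1 (edgeR adjusted p of 0.101). The TEML1ox call of PtXaAlbH.11G031500.v5.1 also ended with RLE scaling and with the replicate number as a block. It ended without either TEML1_1ox replicate, TEML1_2ox replicate 1 or TEML2_1ox replicate 1 at SD8, and without replicate 1 of TEML1_1ox, TEML1_2ox or WT, either TEML2_1ox replicate or TEML2_2ox replicate 2 at CH2 (edgeR adjusted p up to 0.241, all alternatives counted). Its TEML2ox call ended also without WT replicate 1 at CH2. The other 5 TEML2ox calls ended also without either WT or either TEML2_2ox replicate at CH2, and all of them but PtXaAlbH.01G328000.v5.1 without WT replicate 2 at SD8. All but PtXaAlbH.05G194300.v5.1 were lost too without TEML2_2ox replicate 2 at SD8. Those of PtXaAlbH.14G005800.v5.1, PtXaAlbH.13G075600.v5.1 and PtXaAlbH.14G087000.v5.1 were lost without replicate 2 of TEML1_2ox or TEML2_1ox at CH2, and the first and last of these also without TEML1_1ox replicate 2 at SD8 and with the replicate number as a block. Over all alternatives run, the edgeR adjusted p of these 5 calls reached 0.286. Of the SD8 libraries left out, the TEML1ox count was 37 without TEML1_2ox replicate 2, 34 and 18 without TEML2_2ox replicates 1 and 2, 9 without TEML2_1ox replicate 2, and 1 without replicate 1 of TEML1_1ox, TEML1_2ox or TEML2_1ox. Of the CH2 libraries, it was 29 without TEML1_1ox replicate 2, 4 without TEML2_2ox replicate 1, and 1 without WT, TEML1_1ox or TEML1_2ox replicate 1, either TEML2_1ox replicate or TEML2_2ox replicate 2. The TEML2ox count was 188 and 4 without TEML2_2ox replicates 1 and 2 at SD8, 146 without TEML2_1ox replicate 1, 117 without TEML1_2ox replicate 1, 16 without TEML1_1ox replicate 2 and 7 without WT replicate 2 at that harvest. At CH2 it was 122 and 6 without TEML1_2ox replicates 1 and 2, 8 without TEML2_1ox replicate 2, 1 without either TEML2_2ox replicate, and 0 and 1 without WT replicates 1 and 2. Without the TEML2_2ox line it was 0. DESeq2 and a model with each line as its own group gave far higher interaction counts for both constructs, listed with the other alternatives below.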

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

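The tests of a mislabelled line and of a shared axis were chosen after the result was seen; the first replaced a test written earlier and never run, and its outcome was first read as in favour and then as open.

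Of 42 groups of values over the libraries of a construct or harvest, 2 had a library far from the others, where chance gives 2.1. TEML1_1ox replicate 1 stood at 8.50 CPM of PtXaAlbH.17G012500.v5.1 at CH2, with the next library at 3.82. TEML1_1ox replicate 2 had a total of 38978339 counts at CH2, with the next TEML1ox library at 38151654.

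The effect of a construct differed between harvests by the interaction test at 2 genes for TEML1ox and 56 for TEML2ox. The named ones were PtXaAlbH.11G031500.v5.1 (1.16 for TEML1ox and 1.39 for TEML2ox on the log2 scale), PtXaAlbH.14G087000.v5.1 (-1.78 for TEML1ox and -1.18 for TEML2ox), and for TEML2ox PtXaAlbH.01G328000.v5.1 (0.98), PtXaAlbH.14G005800.v5.1 (1.33), PtXaAlbH.05G194300.v5.1 (-1.56) and PtXaAlbH.13G075600.v5.1 (-1.48). Lines of 1 construct differed by direct test at 6 genes (TEML1ox, SD8), 5483 genes (TEML2ox, SD8), 20 genes (TEML1ox, CH2) and 17 genes (TEML2ox, CH2).

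TEML2_2ox stood apart from the other lines at SD8. The data argue against depth, since thinning every SD8 library to the smallest total left 6255 genes between TEML2_2ox and WT, against 6353. The marker test alone left a mislabelled line open. Genes that marked single lines at CH2 placed 9 of the 10 SD8 libraries in their own line. But 1 of the 2 TEML2_2ox libraries went to TEML1_1ox, by a score of 0.26 over 0.20 with 9 markers for TEML2_2ox. Other values argue against a swap. PtXaAlbH.08G098800.v5.1 was at 250.3 and 250.6 CPM in these libraries, against 38.8 or below in WT and both TEML1ox lines. PtXaAlbH.10G102000.v5.1 was at 10.3 and 10.1 CPM, against 126.6 or above in the TEML1ox lines. On the TEML2_1ox markers they scored -0.31 and -0.52, against 0.78 and 0.88 in the TEML2_1ox libraries. A candidate explanation is an axis on which replicate libraries vary at SD8, and whether its source lies in the plants or in handling was not tested. Across genes, the TEML2_2ox minus TEML2_1ox difference correlated with the difference between replicates at r = 0.61 in TEML1_1ox, 0.33 in TEML1_2ox and -0.51 in WT. The sign is arbitrary and genes are not independent replicates. A difference of the line itself, including its higher level of PtXaAlbH.08G098800.v5.1, remains untested.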

How the results depend on the processing

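The fit without the TEML2_2ox line was chosen after the data were seen. The WT chilling count stayed within 1.5 times of 16776 under every alternative run. No named gene changed direction under DESeq2, RLE, the replicate block or any library left out, where 306 values still passed the threshold and 93 did not. At 35779227 counts or more per library, depth limits the genes at 0 in a group, whose folds are lower bounds. Alternatives on the gene lists were not run because the lists were void. Where a count moved, the cause was not tested, except that leaving out libraries or a line leaves fewer samples.

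In the order TEML1ox and TEML2ox against WT at SD8, TEML1ox against TEML2ox at SD8, the same 3 at CH2, and the interactions of TEML1ox and TEML2ox (0, 0, 1, 959, 1609, 26, 2 and 56 as reported), DESeq2 called 71, 208, 46, 2024, 2709, 390, 415 and 802 genes, and each line as its own group 73, 1144, 94, 1899, 2649, 199, 341 and 1422. Without the TEML2_2ox line they were 1, 6, 3, 537, 46, 12, 37 and 0. At an adjusted p under 0.01, TEML1ox against TEML2ox gave 0 at SD8 and 2 at CH2, the constructs against WT at CH2 112 and 245, and the interactions 1 and 1. The fit of all 20 libraries gave 14 and 49 genes against WT at SD8 and 277 (211 higher, 66 lower) and 695 (474 higher, 221 lower) at CH2. With the line as a random block limma-voom gave 323 and 767 at CH2. Plain limma-voom gave 2 genes for TEML1ox against TEML2ox at SD8. The TEML1ox interaction was 1 gene under RLE, limma-voom and the stricter filter. Genes in both lines at SD8 (10 and 23) were 155 and 96 with DESeq2 and 1 and 7 at 0.01. For TEML1ox they were 20 with no filter and 2 without TEML2_2ox. At CH2 (543 and 722) they were 71 and 35 at 0.01.

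With the replicate number as a block, TEML1ox against WT at CH2 gave 578 genes, TEML1ox against TEML2ox 0 at SD8 and 10 at CH2, the interactions 1 and 16, and genes in both lines at CH2 344 and 450. The numbers do not pair the samples: replicate differences correlated between lines from -0.15 to 0.19 at SD8 and from -0.11 to 0.12 at CH2, with 1 of 10 pairs of lines over 0.1 at each harvest.

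Leaving out each library in turn, a lone WT library being assumed to vary like the other groups, gave 0 to 1 and 0 to 5 genes for TEML1ox and TEML2ox against WT at SD8, 0 to 1 between the constructs at SD8, 11 to 1373 and 24 to 2203 against WT at CH2, and 2 to 68 between the constructs at CH2. It gave 14232 to 17086 for chilling in WT and 0 to 37 and 0 to 188 for the interactions. Genes in both lines ran from 2 to 270 and 7 to 59 at SD8 and from 29 to 610 and 12 to 979 at CH2. Both lowest CH2 counts against WT came without WT replicate 1.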

Other observations

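The tests of all-or-none genes, of the overexpressed transcript and of a shift towards the chilled state were chosen after the result was seen. Those of all-or-none genes replaced tests written earlier and never run. The tests of reads credited to neighbouring genes, of called genes lying next to each other, of the TEML1ox transcript, of a difference present before chilling and of a shift towards the chilled state were first read as decisive and, once their values were seen, as open.

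Among genes that chilling lowered in the other construct, few were lower in the overexpressors than in WT at CH2. For TEML1ox 2.29% of 9597 such genes were higher and 0.698% lower, against 2.45% and 2.20% of the 9695 genes that chilling raised. For TEML2ox 3.27% of 9248 lowered genes were higher and 1.45% lower, against 4.11% and 4.44% of the 9496 raised genes. Among genes not called for chilling, 2.14% were higher and 1.31% lower for TEML1ox, and 2.80% and 2.41% for TEML2ox. No test compared these shares, and the gene groups were not matched for expression level. Of the 3469 genes higher in TEML2_2ox at SD8, chilling lowered 57.1% in TEML1ox and raised 14.4%, where it lowered 37.1% and raised 34.8% of all genes tested. Of the 2884 lower ones it raised 47.3% and lowered 28.3%.

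WT stood apart from all 4 lines at CH2. The WT pair against the other 8 libraries gave 1358 genes, and 1 of the 45 pairs, the real one, gave that many, with 14 the highest of the others, so chance assignment of single libraries can be excluded. The highest of the 4 line pairs also gave 14. The 8 libraries set against a line pair included WT, whose difference adds to their spread, so that count is not like the WT one. With each line as its own group, the lines differed from WT at 972 to 2225 genes. Lines of a construct differed from each other at 20 and 17 genes, which argues against a difference of that kind alone. But only 5 of the pairs keep lines together, too few for a share under 0.05. What stays open is anything that WT plants did not share with transformed ones, as the labels describe no empty-vector control, and the constructs themselves, which may both contribute. At SD8 the WT pair gave 1 gene and 7 of the 45 pairs gave as many, so chance cannot be excluded there, and the TEML2_2ox pair gave 4899, which points to a structure of the samples other than WT against the rest.

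Between the constructs, 1 of the 35 splits of the 8 libraries at CH2, the real one, gave as many as 26 genes, and the highest other gave 1, so chance assignment of single libraries can be excluded there. Only 3 of the 35 splits keep both libraries of each line together, too few for a share under 0.05 between lines, and they gave 26, 1 and 1 genes. At SD8 3 of the 35 splits gave as many as the real 1 gene and the highest other gave 1789, with both TEML2_2ox libraries on one side, so chance cannot be excluded.

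In 6 genes every library held either 0 to 1 or at least 50 counts, with at least 2 libraries of each kind, among them PtXaAlbH.18G093200.v5.1 and PtXaAlbH.07G094900.v5.1, named in the report. All 6 were split in at least 1 replicate pair, so neither a fixed difference between lines nor the harvest alone accounts for them. That fixed the other outcomes in advance: 0 of the 6 was constant within every line and 0 split by harvest. A partial role of the harvest was not tested. PtXaAlbH.01G158600.v5.1 held at least 50 counts in 10 SD8 and 3 CH2 libraries, and PtXaAlbH.18G003900.v5.1 in 8 and 10. Loss of reads to a neighbouring listed gene stays open for all 6. The median share regained by the 3 listed genes on each side was 1.09. In 5 of the 6 the neighbours' own spread exceeded the missing counts, the 2 named genes included, at shares of -0.0746 and 0.0844. In the sixth gene the spread was 0.0277 of the missing counts, measured at SD8 only. Its share regained, 0.222, is a mean over both harvests, with 1 library holding counts at CH2. The spread and the share thus cover different libraries and do not decide the question. How the reads were counted or assigned may be the source, and no biological explanation was tested.

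The transcript of the overexpressed coding sequence is a candidate source of genes higher in every library of a construct. At least 2-fold higher in all 8 libraries than in the 12 others at both harvests was 1 gene for TEML2ox, PtXaAlbH.08G098800.v5.1, and 0 for TEML1ox. PtXaAlbH.10G102000.v5.1 was higher in all 8 TEML1ox libraries at both harvests but under 2-fold at CH2. The identifiers carry no names, and a sequence unlike every listed gene would not be counted, so the TEML1ox case is left open.

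Whether overexpressor buds were already shifted towards the chilled state before chilling stays open. A score of chilling-raised minus chilling-lowered genes, taken from the other construct, was lower in the overexpressors than in WT at SD8. The differences were -0.26 for TEML1ox and -0.32 for TEML2ox on the log2 scale. The exact permutation p was 0.267 and 0.2, with 0.0667 the smallest that 15 regroupings allow. At CH2 the score was also lower than in WT, at 3.89 against 4.11 for TEML1ox and 3.79 against 3.92 for TEML2ox. The SD8 direction was opposite to such a shift but under 2 standard errors (0.175 and 0.174) from 0. These errors took libraries of a line as independent. The choice of genes also favours that sign at SD8. Each list came from the other construct's change between harvests, and the constructs shared deviations from WT at SD8 (covariance 0.251 against 0.0509 simulated). The sign is thus no evidence against a shift. The TEML2ox difference at SD8 includes TEML2_2ox, which stood apart at that harvest, and this score was not run without that line. The genes called at CH2 in both constructs, scored in the SD8 libraries, differed between overexpressors and WT by 0.20 with an exact permutation p of 0.244 over 45 pairs, so whether the difference was present before chilling stays open, since a p that misses the threshold excludes nothing. The TEML2_2ox libraries, at 1.23 and 0.95, made much of it: the other 6 overexpressor libraries ran from 0.61 to 0.76 and WT stood at 0.63 and 0.56, a difference of 0.10 without that line (exact permutation p of 0.179 over 28 pairs, 0.0357 the smallest possible). Across genes, which are not independent replicates, the SD8 and CH2 fold changes against WT correlated at r = 0.22 for TEML1ox and 0.12 for TEML2ox, and 59.4% and 54.4% of the CH2 calls had the same sign at SD8, while the constructs correlated with each other at SD8 at r = 0.78, against 0.68 simulated with no effect.

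Whether called genes sit next to each other at CH2 stays open. TEML2ox had 61 neighbouring pairs called in one direction, where 1000 permutations averaged 50.7 and reached 72 (1-sided permutation p of 0.0769), and TEML1ox had 22, where they averaged 18.6 and reached 31 (p of 0.238). Lying within the range of the permutations was first taken to exclude such runs, but both counts lay above the averages, so it does not.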
